A study of Mus musculus with 13 samples.

How the data were processed

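Total RNA from inguinal white adipose tissue of 13 mice was sequenced. The labels state that tissue came from individual mice and that mice were allotted to groups at random with matched weights, so each library was taken as 1 animal. The deposited table gives FPKM per gene with gene names, coordinates and lengths. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were named, without a role or order, along with the mouse build mm8. Of the table's 54532 gene identifiers, 54409 were in the annotation of GRCm38 used here and 53499 had the same start and end there, so coordinates are given as the table lists them, on GRCm38. Strand setting and annotation version are not given in the sources used here.

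Each deposited FPKM value was multiplied by its gene length and divided by the smallest step of its library, and 100% of values were then whole within a tolerance of 0.05. Recovered totals were 14815592 to 18303302 reads per library. The total that the FPKM values imply as divisor was 0.479 to 1.23 times the library's own recovered total, and FPKM sums differed 5.03-fold between libraries. The origin of this divisor is not given in the sources used here. Counts of genes that share reads with near-identical copies are uncertain: Gapdh was listed at 0.337 to 4.77 FPKM while Actb was at 168 to 661 FPKM. Ribosomal protein genes, haemoglobin genes and overlapping or antisense genes carry the same doubt.

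Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the changes of low genes. Genes with an FPKM of at least 1 in at least 3 libraries were kept (14421). Limma 3.58.1 in R 4.3.3 fitted group means to all 13 libraries, with the trend and robust options of eBayes, two-sided tests and Benjamini-Hochberg adjustment over all genes kept, at a threshold of 0.05. The comparisons were SF_ConD against SC_ConD, SF_HPD against SF_ConD and SF_HPD against SC_ConD. Camera tested 33 gene lists with at least 5 members kept, at a preset correlation of 0.01 and then with an estimated correlation, and fry was run as another alternative. The design, these lists, the rule for named genes and most alternatives were fixed before the data were examined. Where a symbol had several identifiers the one with the highest mean was used.

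The rule for named genes took the 8 largest rises and falls among genes that passed, with a mean of at least 2 FPKM and no overlap between the groups, without unnamed gene models, pseudogenes and antigen receptor segments. Where fewer than 5 passed in a direction, the 5 with the smallest p that met the other criteria were named and said not to pass. Up to 4 members of each list described were named by smallest p in the direction of the list, along with 7 preset genes (Lep, Adipoq, Ucp1, Tnf, Il6, Ccl2 and Adgre1). Il6 was not kept by the filter on low values. The values of some genes that the rule names are not reported here. Each preset gene also had an exact two-sided permutation test.

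The limma steps were tested on simulated reads with 200 changed genes and a smoother spread than the real libraries show. These reads were drawn independently for each gene around a common profile, with the same dispersion for all genes. They hold no differences between libraries in tissue content or transcript length, so the shares recovered do not measure the power in the real libraries. For SF_ConD against SC_ConD they recovered 49.0% of genes changed 4-fold and 2.02% of those changed 2-fold on 14632 genes, with 61 calls of which 11 were false. For SF_HPD against SF_ConD they recovered 81.3% and 8.08% on 14655 genes, with 88 calls of which 6 were false. For SF_HPD against SC_ConD they recovered 64.3% and 3.26% on 14637 genes, with 71 calls of which 5 were false. In the real data the median SE of a log2 fold change was 0.47, 0.41 and 0.47 in these comparisons.

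Library pairs were compared for duplicates over genes with at least 10 reads. The lowest chi-square per degree of freedom was 96.5 within a group and 71.0 over all pairs, so no pair differed by as little as sampling noise. The labels number the replicates in each group, and whether same-numbered libraries deviated together from their group means was checked by correlation across genes. Between SC_ConD and SF_HPD the 3 correlations were 0.711, 0.333 and 0.191, each over 0.1, so the numbers were treated as pairing these groups. The labels describe individual mice and give no source of a pairing, and only 1 of the 3 correlations was highest with its own number. That pair, SC_ConD 1 and SF_HPD 1, also leaned alike toward long transcripts (Spearman rho 0.559 and 0.563). A pairing by number is therefore not established. The report gives the values with the replicate number as a block where they changed a call in SF_HPD against SC_ConD.

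Alternatives were a pseudocount of 0.1, no filter beyond an FPKM above 0, a mean FPKM of at least 5, rescaling to TPM, median-of-ratios and quantile scaling, eBayes without trend and robust, array weights, the replicate block, only the groups compared, a minimum fold change and each library left out. Chosen after seeing the data were limma-voom on the recovered reads, sets of libraries left out for lymphoid, liver, adipocyte or muscle transcripts, covariates for the transcript-length trend and for tissue scores, and lists of liver, lymph node vessel and Y-linked markers. Python 3.11.15 and matplotlib 3.10.9 drew the figures.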

Results

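Total RNA from inguinal white adipose tissue, the subcutaneous fat pad of the groin, was sequenced from individual mice, collected after 12 h of fasting. The 13 libraries fell into 3 groups. SC_ConD held 3 mice with undisturbed sleep on chow, SF_ConD 5 mice with fragmented sleep on chow, and SF_HPD 5 mice with fragmented sleep on a high-protein diet. The diet supplied 50% of its energy as protein, 12% as fat and 38% as carbohydrate. The title of the study names chronic sleep fragmentation, a high-protein diet and inflammation of adipose tissue. Reads on genes, recovered from the deposited FPKM values, ran from 14815592 in SF_HPD 4 to 18303302 in SF_ConD 4. Of 54532 genes, 14421 reached an FPKM of at least 1 in at least 3 libraries and were tested.

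Transcripts of tissues other than fat differed strongly between libraries of the same group. Alb, the serum albumin gene of liver, was at 4223 FPKM in SC_ConD 2 and 1614 FPKM in SC_ConD 3. In SC_ConD 1 it was at 52.2 FPKM, and in the 10 sleep-fragmented libraries at no more than 88.3 FPKM. Markers of B cells and lymph nodes had a mean log2(FPKM + 1) between 4.36 and 5.17 in SF_ConD 1, 4 and 5 and SF_HPD 4 and 5, and between 0.38 and 1.45 in the other 8 libraries. Those 5 libraries are called lymphoid-rich here. Glycam1, a gene of the vessels through which lymphocytes enter lymph nodes and also of mammary epithelium, was at 124 to 1545 FPKM in them and at no more than 0.796 FPKM in the rest. Acta1, the actin of skeletal muscle, reached 6792 FPKM in SF_HPD 4 and 1306 FPKM in SC_ConD 3. The adipocyte identity genes had a mean log2(FPKM + 1) of 3.73 in SF_HPD 2 and of at least 6.93 in each of the other 12 libraries. Mitochondrially encoded genes took 2.82% of the reads of SF_HPD 1 and 33.2% of those of SF_ConD 5.

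**Figure D1:**
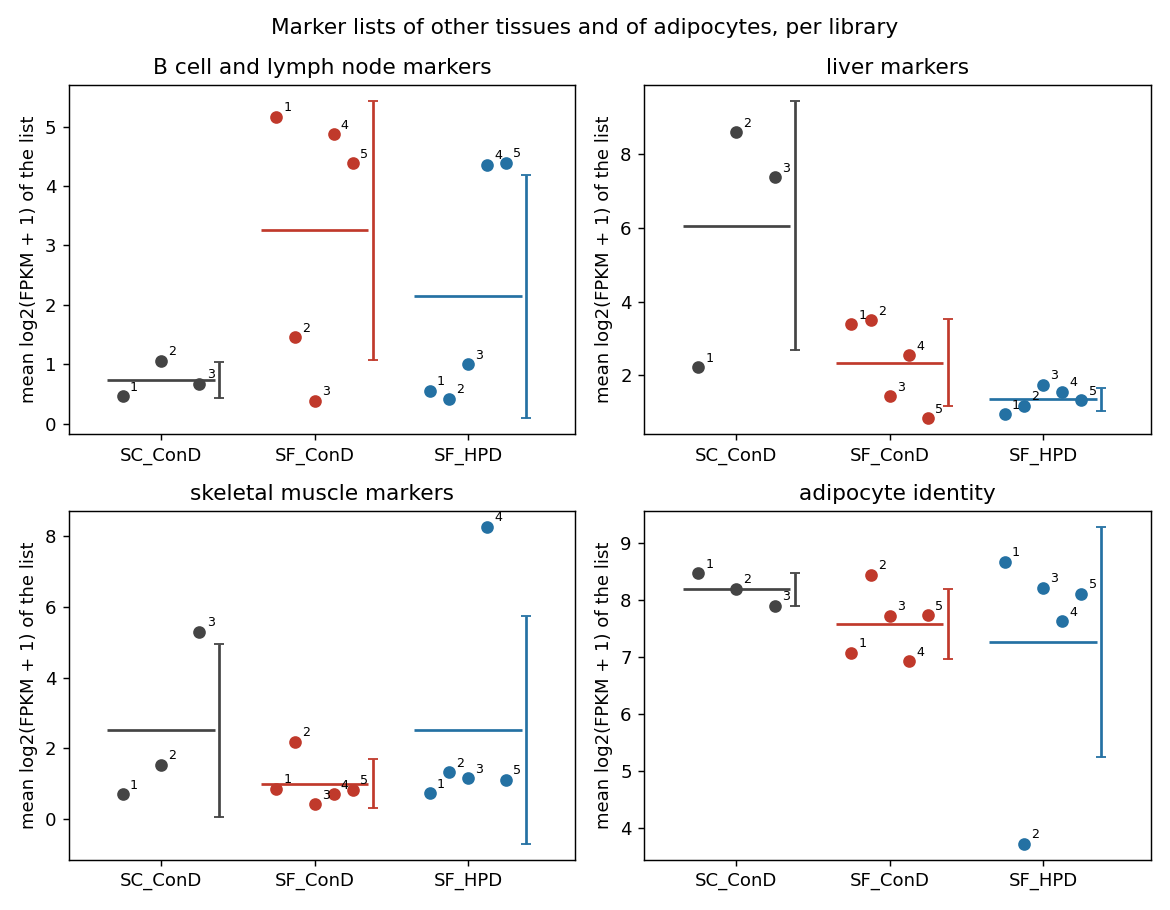
Mean log2(FPKM + 1) of 4 gene lists (vertical axes) in each library by group; each point is a library labelled with its replicate number, horizontal lines are group means and bars are 1 SD. Liver markers stood at 8.58 in SC_ConD 2 and 2.22 in SC_ConD 1, and the adipocyte identity list at 3.73 in SF_HPD 2.

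SF_ConD against SC_ConD asked what sleep fragmentation on chow did to the tissue. At the preset correlation, lists of lymphocyte markers and of cell division genes lay higher in the sleep-fragmented mice. Lists of cholesterol synthesis, extracellular matrix and protein folding genes lay lower. In the B cell list SF_ConD 3 (mean log2(FPKM + 1) 0.38) lay below each SC_ConD library. In protein folding genes SC_ConD 1 (4.47) lay below each SF_ConD library, and in cholesterol synthesis (2.49) within their range of 2.24 to 2.73. Of these lists only the matrix list had no overlap between the groups. No single gene passed, and no list was called with an estimated correlation between its genes. The adipokine gene Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877 on GRCm38) was at 6.42 ± 5.82 FPKM (SD, n = 5) in SF_ConD and 44.3 ± 25.2 FPKM (SD, n = 3) in SC_ConD, without overlap. An exact two-sided permutation test of Lep gave p = 0.0179, the smallest that 56 regroupings allow, and 0.125 after Benjamini-Hochberg adjustment over the 7 preset genes.

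Camera at a preset correlation of 0.01 called 10 of 33 lists, 4 higher and 6 lower in SF_ConD. A list's mean is that of its genes' log2 fold changes, brackets after a gene hold its log2 fold change and SE, and brackets after a library hold the list's mean without it. A list's direction is that of its camera test against the other genes, so it can turn while the mean keeps its sign. B cell and lymph node markers had positive fold changes in 17 of 17, 4 of them with an unadjusted p under 0.05, and included the immunoglobulin gene Ighd (4.29, SE 1.69) and Cxcl13 (3.55, SE 1.52), the chemokine of lymphoid follicles. Their mean was 2.65 (adjusted p = 8.19e-11; adjusted p = 0.610 with an estimated correlation). The B cell mean moved to 0.20 without the lymphoid-rich libraries. Among T and NK cell markers, 18 of 19 fold changes were positive, 6 with an unadjusted p under 0.05, and the list included the killer cell receptor gene Klrb1c (0.91, SE 0.39) and the T cell kinase gene Zap70 (2.31, SE 0.999). The mean was 1.83 (adjusted p = 6.99e-09; adjusted p = 0.660 with an estimated correlation). The T and NK cell call ended without the lymphoid-rich libraries (-0.0916). MHC class II genes, which present antigen, had positive fold changes in 10 of 10, 0 of them with an unadjusted p under 0.05, and included H2-DMb2 (3.16, SE 1.60) and H2-Ob (2.88, SE 1.47). Their mean was 1.39 (adjusted p = 0.00492; adjusted p = 0.836 with an estimated correlation). The MHC class II call ended without SC_ConD 1 (0.92), and its direction turned without the lymphoid-rich libraries (-0.58). The MHC class II mean moved to 2.31 without SC_ConD 2 and 3. Among cell cycle genes, 18 of 19 fold changes were positive, 5 with an unadjusted p under 0.05, and the list included the mitotic cyclin Ccnb2 at 3.21 ± 1.77 FPKM against 0.116 ± 0.201 FPKM (SD, n = 5 and 3) and the spindle gene Tpx2 (0.79, SE 0.29). The mean was 0.75 (adjusted p = 1.76e-09; adjusted p = 0.593 with an estimated correlation). The cell cycle mean moved to 0.22 without the lymphoid-rich libraries.

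On the lower side, Dhcr7, the gene of a late reductase of cholesterol synthesis, was at 1.42 ± 0.442 FPKM against 3.84 ± 2.09 FPKM (SF_ConD against SC_ConD, SD, n = 5 and 3). Cholesterol synthesis genes had negative fold changes in 18 of 19, 9 of them with an unadjusted p under 0.05, and included Dhcr7 (-0.92, SE 0.33). Their mean was -0.83 (adjusted p = 2.55e-08; adjusted p = 0.593 with an estimated correlation). The cholesterol call ended without SC_ConD 2 and 3 (-0.14), and the mean moved to -0.51 without SC_ConD 2. Among matrix and fibrosis genes, 20 of 22 fold changes were negative, 3 with an unadjusted p under 0.05, and the list included fibronectin Fn1 (-2.997, SE 0.63) and thrombospondin Thbs1 (-2.24, SE 0.61). The mean was -0.85 (adjusted p = 4.95e-05; adjusted p = 0.660 with an estimated correlation). The matrix call ended without SC_ConD 1 (-0.54), and the mean moved to -1.46 without SC_ConD 2 and 3. Unfolded protein response genes had negative fold changes in 14 of 15, 2 of them with an unadjusted p under 0.05, and included the chaperone genes Hyou1 (-1.27, SE 0.47) and Hspa5 (-1.08, SE 0.48). Their mean was -0.44 (adjusted p = 0.00192; adjusted p = 0.610 with an estimated correlation). The unfolded protein call ended after TPM rescaling (-0.21) and without SC_ConD 2 (-0.16), and its direction turned without SC_ConD 2 and 3 (0.19). The unfolded protein mean moved to -0.76 without SC_ConD 1. Among skeletal muscle markers, 12 of 12 fold changes were negative, 1 with an unadjusted p under 0.05, and the list included Acta1 (-5.01, SE 1.87). The mean was -2.06 (adjusted p = 0.00505; adjusted p = 0.836 with an estimated correlation). The muscle call ended without SC_ConD 3 (-0.18), and its direction turned without SC_ConD 2 and 3 (0.42). The muscle mean moved to -3.29 without SC_ConD 1. Amino acid stress response genes had negative fold changes in 13 of 17, 1 of them with an unadjusted p under 0.05, and included Cth (-1.19, SE 0.42) and the stress hormone gene Gdf15 (-1.67, SE 0.82). Their mean was -0.51 (adjusted p = 0.0127; adjusted p = 0.610 with an estimated correlation). The stress response call ended without SF_ConD 3 (-0.44), SC_ConD 2 (-0.32), SC_ConD 3 (-0.44), the lymphoid-rich libraries (-0.51) and SC_ConD 2 and 3 (-0.00476). Among nuclear genes of oxidative phosphorylation, 36 of 39 fold changes were negative, 0 with an unadjusted p under 0.05, and the list included Ndufa9 (-0.55, SE 0.49) and Ndufa4 (-0.90, SE 0.84). The mean was -0.37 (adjusted p = 0.0198; adjusted p = 0.836 with an estimated correlation). The oxidative phosphorylation call ended without SF_ConD 3 (-0.22), SF_ConD 4 (-0.28) and the lymphoid-rich libraries (-0.32), and its direction turned without SC_ConD 2 (0.0822) and SC_ConD 2 and 3 (0.44). The oxidative phosphorylation mean moved to -0.78 without SC_ConD 1. SC_ConD 2 and 3 were the libraries with liver transcripts, and without them the 1 SC_ConD library left was assumed to vary like the other groups.

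With an estimated correlation camera called 0 of 33 lists, 2 having an unadjusted p under 0.05, and fry called 0, with 3 under 0.05 and a smallest adjusted p of 0.427. Over the alternatives run, the highest adjusted p of each of these 10 lists lay between 0.593 and 0.949, and the lowest between 1.97e-16 and 0.00370. Libraries also differed in how far their expression leaned toward long transcripts, a length trend that was above 0.3 in SF_HPD 1 and 4, SF_ConD 3 and SC_ConD 1. Among the other 9 libraries, where SC_ConD holds only SC_ConD 2 and 3, the matrix call ended (-0.57). Adjusted over the list alone, 4 genes passed, among them Fn1 and Thbs1 in the matrix list and Ccnb2 in the cell cycle list, while over all genes none did. That adjustment does not correct for the 33 lists examined. Inflammatory mediators (mean -0.32) and macrophage markers (mean -0.13) were not called (adjusted p = 0.355 for each). Signs differed for heat shock genes (mean -0.17, median 0.01, test downward) and immediate early genes (mean -0.07, median -0.04, test upward), and neither list was called.

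Limma called 0 of 14421 genes, with a smallest adjusted p of 0.716. At an unadjusted p under 0.05 there were 828 genes, against 721 expected if p values were uniform, and limma-voom on recovered reads called 0, with 614. The gene with the smallest p was Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), which liver also secretes, at 4.90 ± 2.55 FPKM (SD, n = 5) in SF_ConD and 59.4 ± 49.1 FPKM (SD, n = 3) in SC_ConD. The other genes on the lower side with the smallest p and no overlap were Lpgat1 (-1.93, SE 0.42), Nkd1 (-1.66, SE 0.40), Cyp4v3 (-1.54, SE 0.37) and the retinaldehyde dehydrogenase gene Aldh1a1 (-2.07, SE 0.52). Their counterparts on the higher side were Snord7 (2.32, SE 0.57), Ccnb2 (1.79, SE 0.45; ENSMUSG00000032218, chromosome 9, 70407692 to 70421547), Them6 (1.84, SE 0.50), the histone gene Hist2h2be (1.51, SE 0.42) and the antiviral deaminase gene Apobec3 (1.47, SE 0.41). Snord7 was listed at 0 in each SC_ConD library and at 0.691 FPKM in SF_ConD 2, so its lack of overlap rests on a value near the floor. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), an inflammatory cytokine gene, was at 1.63 ± 1.12 FPKM (SD, n = 5) in SF_ConD and 0.0845 ± 0.146 FPKM (SD, n = 3) in SC_ConD. Its exact two-sided permutation p of 0.0357 became 0.125 after adjustment. Tnf stood at 3.27, 2.05 and 1.65 FPKM in the lymphoid-rich SF_ConD 1, 4 and 5 and at 0.491 and 0.701 FPKM in SF_ConD 2 and 3, so within SF_ConD it followed the lymphoid transcripts. The other preset genes did not pass, with log2 fold changes of -1.01 (SE 0.73) for the chemokine Ccl2, -0.41 (SE 0.66) for the macrophage gene Adgre1, -0.87 (SE 1.25) for adiponectin Adipoq and 0.69 (SE 1.48) for the uncoupling protein Ucp1. With single libraries left out these ran from -2.11 to -0.39, -0.70 to -0.15, -1.35 to -0.40 and -0.41 to 1.89. Of 9545 named genes with a mean of at least 2 FPKM, 312 had no overlap between the groups, and chance gives 3.57%. Without SC_ConD 1 limma called 194 genes, 189 of them higher in SC_ConD, and these calls held 21 of the 22 liver markers.

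**Figure D2:**
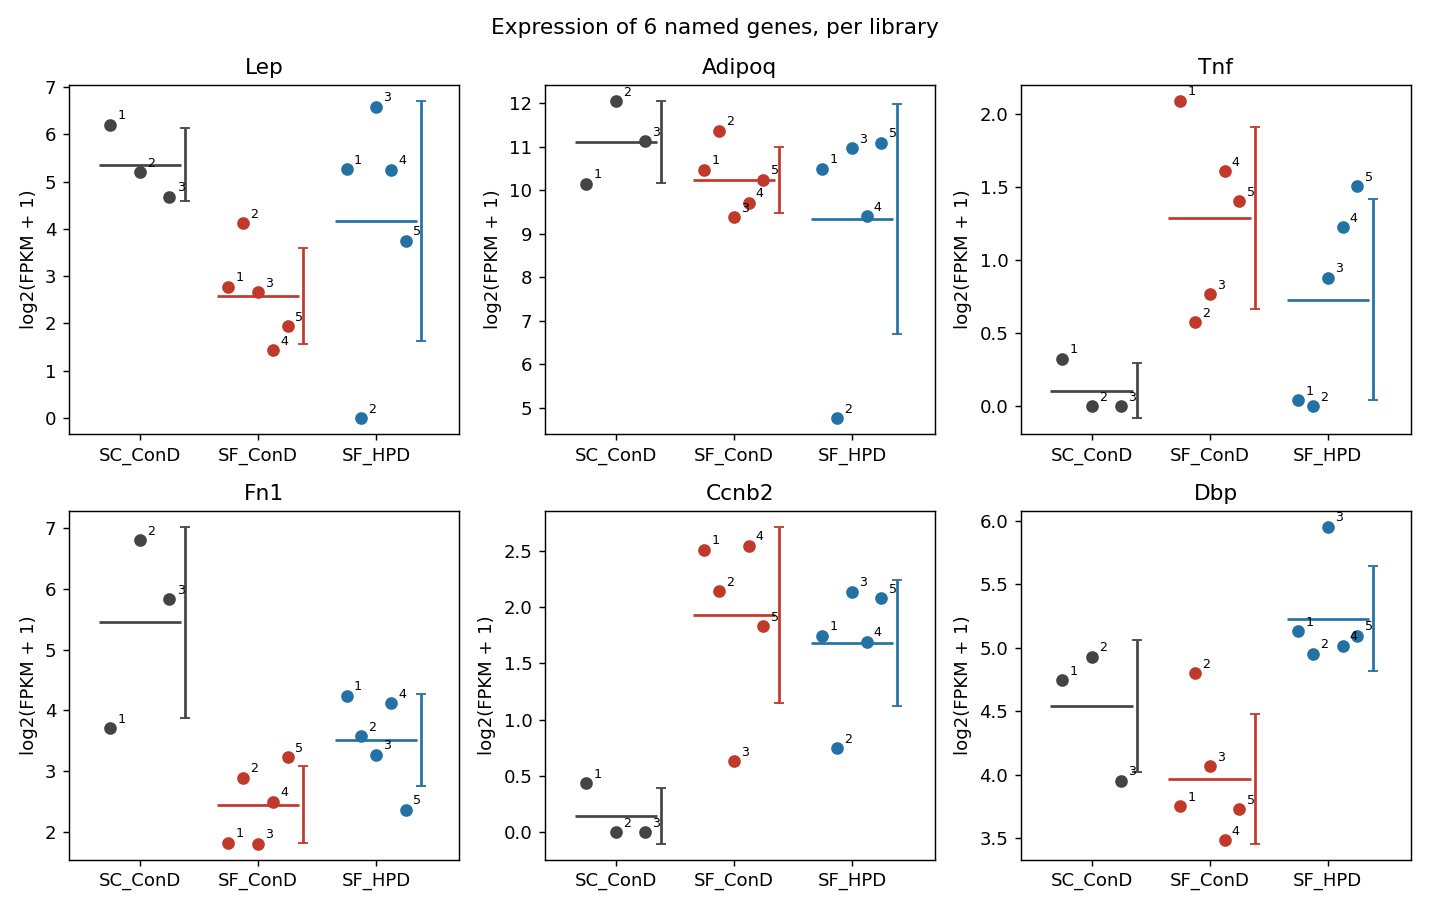
Log2(FPKM + 1) of 6 genes (vertical axes) in each library by group; points are libraries labelled with replicate numbers, lines are group means and bars are 1 SD. Lep lay lower in each of the 5 SF_ConD libraries than in the 3 SC_ConD libraries, and Fn1 reached 110 FPKM in SC_ConD 2.

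SF_HPD against SF_ConD asked what the high-protein diet did in mice with fragmented sleep. Lists of collagens and other matrix genes lay higher on the diet, and lists of lymphocyte markers, interferon-stimulated genes, epithelial markers and mitochondrially encoded genes lay lower. No single gene passed, and no list was called with an estimated correlation. The fibrillar collagen genes Col3a1 and Col1a2 were at 74.6 ± 39.8 FPKM against 19.5 ± 12.8 FPKM and at 35.1 ± 23.8 FPKM against 9.40 ± 5.57 FPKM (SF_HPD against SF_ConD, SD, n = 5 each). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), an output gene of the circadian clock, was at 37.9 ± 12.99 FPKM against 15.5 ± 6.64 FPKM (SD, n = 5), without overlap.

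Camera at the preset correlation called 12 of 33 lists, 4 higher and 8 lower in SF_HPD. Matrix and fibrosis genes had positive fold changes in 19 of 22, 5 of them with an unadjusted p under 0.05, and included Col3a1 (1.92, SE 0.53) and Col1a2 (1.70, SE 0.48). Their mean was 0.80 (adjusted p = 5.94e-09; adjusted p = 0.732 with an estimated correlation). The matrix mean moved to 0.52 without SF_HPD 1. In SF_HPD the matrix list stood at 5.12 and 4.57 in SF_HPD 1 and 4, which have a length trend above 0.3, and at 2.90 to 4.36 in SF_HPD 2, 3 and 5. Among the 9 libraries of lower trend the matrix call ended (0.26, adjusted p = 0.144), and with the trend as a covariate it stayed (0.70, adjusted p = 1.07e-06). Among stromal progenitor markers, 10 of 16 fold changes were positive, 2 with an unadjusted p under 0.05, and the list included Pi16 (1.31, SE 0.44) and Clec3b (1.17, SE 0.53). The mean was 0.34 (adjusted p = 0.00797; adjusted p = 0.732 with an estimated correlation). The stromal call ended without SF_HPD 3 (0.16) and SF_ConD 3 (0.15), and the mean moved to 0.64 without the lymphoid-rich libraries. Skeletal muscle markers had positive fold changes in 12 of 12, 1 of them with an unadjusted p under 0.05, and included Acta1 (3.87, SE 1.62). Their mean was 1.90 (adjusted p = 1.15e-04; adjusted p = 0.732 with an estimated correlation). The muscle call ended without SF_HPD 4 (0.11) and SF_HPD 2 and 4 (-0.0303), and its direction turned without the lymphoid-rich libraries (-0.38). Among cholesterol synthesis genes, 16 of 19 fold changes were positive, 0 with an unadjusted p under 0.05, and the list included the mevalonate kinase gene Mvk (0.83, SE 0.53). The mean was 0.26 (adjusted p = 0.0132; adjusted p = 0.732 with an estimated correlation). The cholesterol call ended without SF_HPD 2 (0.0506), the lymphoid-rich libraries (0.27) and SF_HPD 2 and 4 (0.0843).

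Lower in SF_HPD were the lymphocyte lists. T and NK cell markers had negative fold changes in 19 of 19, 2 of them with an unadjusted p under 0.05, and included Klrb1c (-0.82, SE 0.33) and the granzyme gene Gzma (-1.74, SE 0.76). Their mean was -1.23 (adjusted p = 5.12e-10; adjusted p = 0.732 with an estimated correlation). The T and NK cell mean moved to -0.82 without SF_ConD 1 and -0.38 without the lymphoid-rich libraries. Among B cell and lymph node markers, 17 of 17 fold changes were negative, 0 with an unadjusted p under 0.05, and the list included Ighd (-1.91, SE 1.47). The mean was -1.23 (adjusted p = 9.70e-06; adjusted p = 0.732 with an estimated correlation). The B cell mean moved to -0.79 without SF_HPD 2, -0.73 without SF_ConD 1, -1.98 without SF_ConD 3, -0.80 without SF_ConD 4 and -0.28 without the lymphoid-rich libraries. MHC class II genes had negative fold changes in 10 of 10, 0 of them with an unadjusted p under 0.05, and included H2-DMa (-1.08, SE 0.83) and H2-DMb1 (-0.83, SE 0.64). Their mean was -1.08 (adjusted p = 2.91e-04; adjusted p = 0.732 with an estimated correlation). The MHC class II call ended without SF_HPD 2 (-0.70) and the lymphoid-rich libraries (-0.20), and the mean moved to -0.63 without SF_ConD 1 and -1.75 without SF_ConD 3. Among interferon-stimulated genes, 20 of 20 fold changes were negative, 1 with an unadjusted p under 0.05, and the list included Ifi44 (-0.60, SE 0.25) and the antiviral regulator gene Irf7 (-1.11, SE 0.52). The mean was -0.59 (adjusted p = 1.96e-08; adjusted p = 0.732 with an estimated correlation). The interferon mean moved to -0.25 without the lymphoid-rich libraries. Cell cycle genes had negative fold changes in 14 of 19, 1 of them with an unadjusted p under 0.05, and included the mitotic kinase genes Aurka (-0.65, SE 0.27) and Plk1 (-0.57, SE 0.29). Their mean was -0.19 (adjusted p = 0.0285; adjusted p = 0.733 with an estimated correlation). The cell cycle call ended after TPM rescaling (-0.0364), without SF_HPD 2 (-0.0604), without SF_ConD 1 (-0.0493), without SF_ConD 4 (-0.0752), without SF_ConD 5 (-0.17) and without SF_HPD 2 and 4 (-0.0883), and its direction turned without the lymphoid-rich libraries (0.20). The cell cycle mean moved to -0.38 without SF_ConD 3. Among epithelial markers, 11 of 12 fold changes were negative, 2 with an unadjusted p under 0.05, and the list included the tight junction gene Cldn3 (-3.26, SE 0.91) and the mammary regulator gene Elf5 (-1.16, SE 0.47). The mean was -1.47 (adjusted p = 5.10e-07; adjusted p = 0.732 with an estimated correlation). The epithelial mean moved to -0.68 without SF_HPD 4 and -0.78 without the lymphoid-rich libraries. Mitochondrially encoded genes had negative fold changes in 13 of 13, 1 of them with an unadjusted p under 0.05, and included mt-Atp6 (-2.52, SE 1.11) and mt-Nd4l (-2.36, SE 1.10). Their mean was -1.16 (adjusted p = 7.59e-05; adjusted p = 0.732 with an estimated correlation). The mitochondrial mean moved to -0.58 without SF_HPD 1. Among de novo lipogenesis genes, 14 of 20 fold changes were negative, 2 with an unadjusted p under 0.05, and the list included Thrsp (-2.39, SE 0.90) and Pnpla3 (-1.80, SE 0.77). The mean was -0.45 (adjusted p = 0.0104; adjusted p = 0.732 with an estimated correlation). The lipogenesis call ended without SF_HPD 2 (-0.11), SF_ConD 2 (-0.18), SF_ConD 3 (-0.41) and SF_HPD 2 and 4 (-0.0554), and the mean moved to -0.72 without SF_HPD 1 and -1.24 without the lymphoid-rich libraries.

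Of these 33 lists camera called 0 with an estimated correlation, 2 having an unadjusted p under 0.05, and fry called 0, with 0 under 0.05 and a smallest adjusted p of 0.936. Over the alternatives run, the highest adjusted p of each of these 12 lists lay between 0.936 and 0.951, and the lowest between 5.78e-16 and 9.55e-04. Besides the matrix call, those of the stromal (0.26), muscle (0.0621), epithelial (-0.0844) and mitochondrially encoded (-0.65) lists ended among the 9 libraries of lower length trend. Adjusted over the list alone, without adjustment over the 33 lists, 4 genes passed, Col3a1, Col1a2, Cldn3 and, in a list that was not called, Dbp. Inflammatory mediators (mean -0.42, adjusted p = 0.0546), neutrophil markers (mean -0.62, adjusted p = 0.0546) and macrophage markers (mean 0.02, adjusted p = 0.662) were not called. Signs differed for brown and beige adipocyte genes (mean -0.11, median 0.15, test upward), amino acid stress response genes (mean 0.01, median -0.03, test downward), heat shock genes (mean 0.05, median -0.04) and immediate early genes (mean 0.05, median 0.04, test downward), and none of these lists was called.

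**Figure D3:**
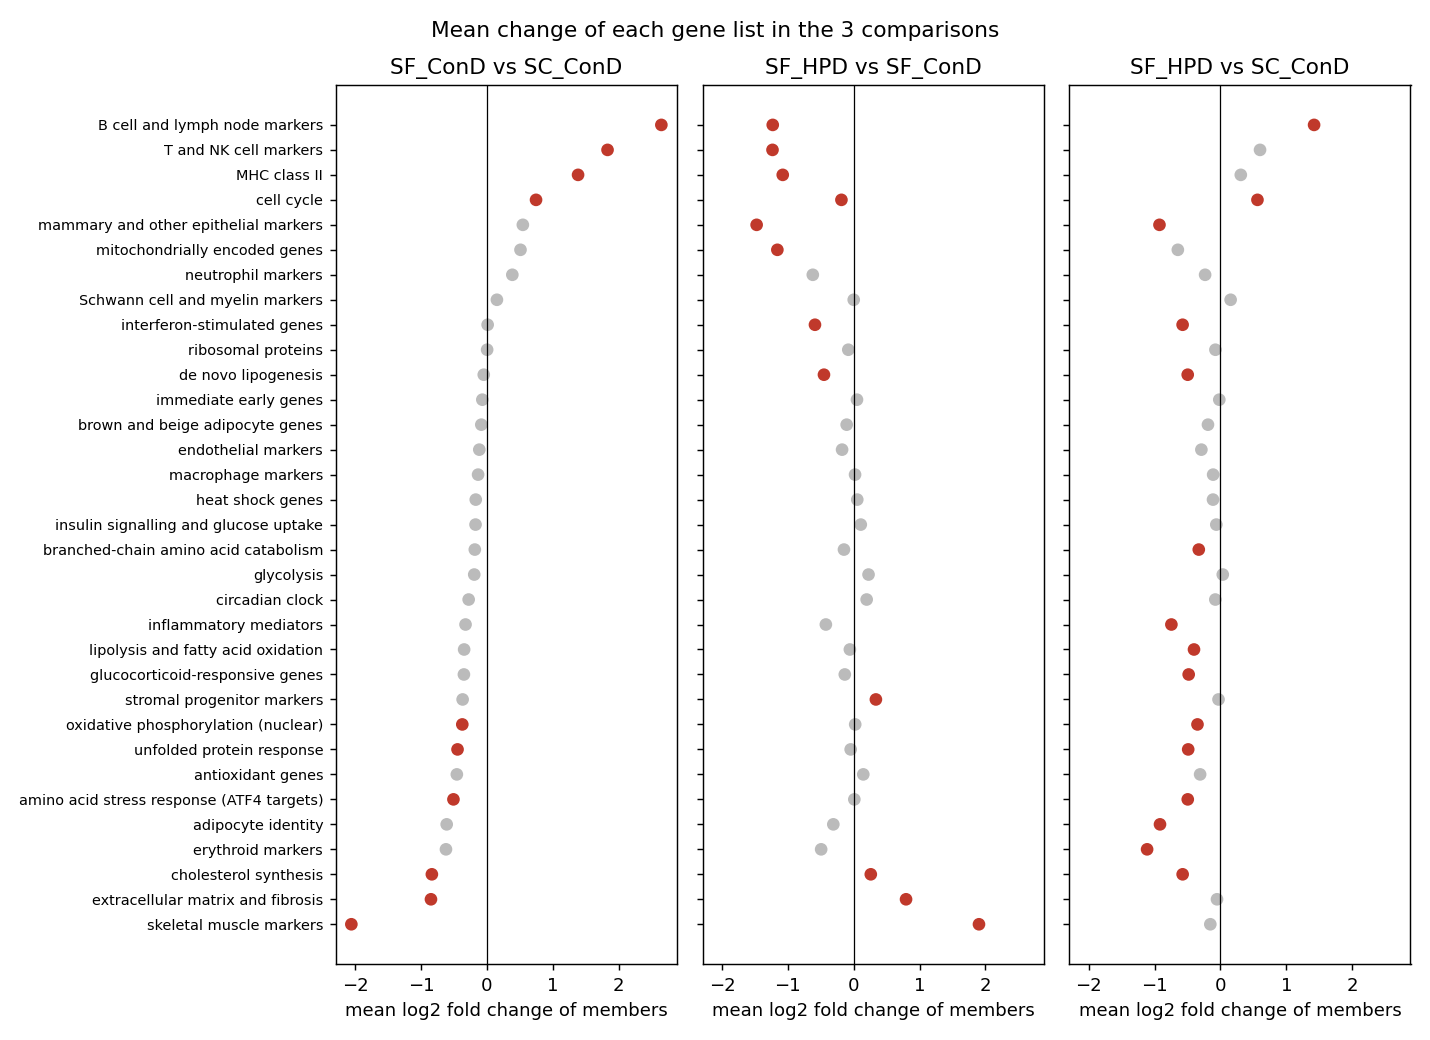
Mean log2 fold change of the members of each of 33 gene lists (horizontal axes) in the 3 comparisons; red points were called by camera at the preset correlation of 0.01 and grey points were not. B cell and lymph node markers had a mean of 2.65 in SF_ConD vs SC_ConD and -1.23 in SF_HPD vs SF_ConD, and 0 lists were called with an estimated correlation, while 2 per comparison had an unadjusted p under 0.05.

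Limma called 0 of 14421 genes between SF_HPD and SF_ConD, with a smallest adjusted p of 0.999994. At an unadjusted p under 0.05 there were 273 genes, against 721 expected if p values were uniform, and limma-voom called 0, with 261. The genes on the higher side with the smallest p among those without overlap were Col14a1 (1.14, SE 0.27; ENSMUSG00000022371, chromosome 15, 55307750 to 55520803), a collagen of fibril surfaces, Dbp (1.26, SE 0.33), Pgm5 (1.11, SE 0.30), Mir22hg (0.998, SE 0.29) and Cyb5d1 (0.81, SE 0.25). On the lower side they were Grrp1 (-1.11, SE 0.29), Lpar6 (-1.01, SE 0.27), the chromatin remodelling gene Smarcd2 (-0.88, SE 0.23), Msc (-0.77, SE 0.22) and Ly6e (-1.58, SE 0.51). Lep was listed at 0 in SF_HPD 2, and its exact two-sided permutation p against SF_ConD was 0.238 over 252 regroupings (0.824 after adjustment over the 7 preset genes). The log2 fold changes of Lep, Tnf, Ccl2, Adgre1, Adipoq and Ucp1 were 1.58 (SE 0.99), -0.56 (SE 0.37), 0.02 (SE 0.63), 0.27 (SE 0.57), -0.89 (SE 1.08) and -0.70 (SE 1.28). With single libraries left out these ran from 0.98 to 2.63, -0.75 to -0.36, -0.23 to 0.25, -0.15 to 0.66, -1.33 to 0.25 and -1.90 to -0.13. Without SF_HPD 2, the library low in adipocyte transcripts, Lep moved to 2.63 and Adipoq turned to 0.25. Of the 9545 named genes 35 had no overlap between the groups, and chance gives 0.794%. Without SF_HPD 5, 1 gene was called, the unnamed model Gm22478 (log2 fold change 1.95, limma adjusted p = 0.0176), named here after its value was seen.

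SF_HPD against SC_ConD set mice with both fragmented sleep and the high-protein diet against undisturbed mice on chow, and the contrast does not separate sleep from diet. At the preset correlation, lists of cell cycle genes and B cell markers lay higher in SF_HPD, and lists of cholesterol synthesis, protein folding, interferon response and fat cell genes lay lower. No list was called with an estimated correlation, and the B cell call also ended with the replicate number as a block. The genes with the smallest p on the lower side, none of which passed, were those of proteins that liver secretes, led by Apoh (ENSMUSG00000000049, chromosome 11, 108343354 to 108414396), a lipid-binding plasma protein. Apoh was at 138 FPKM in SC_ConD 2 and 51.5 FPKM in SC_ConD 3, but at 3.13 FPKM in SC_ConD 1.

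Camera at the preset correlation called 15 of 33 lists, 2 higher and 13 lower. Cell cycle genes had positive fold changes in 18 of 19, 3 of them with an unadjusted p under 0.05, and included Ccnb2 (1.54, SE 0.45) and Tpx2 (0.86, SE 0.29). Their mean was 0.56 (adjusted p = 4.00e-06; adjusted p = 0.573 with an estimated correlation). Among B cell and lymph node markers, 17 of 17 fold changes were positive, 0 with an unadjusted p under 0.05, and the list included Cxcl13 (2.34, SE 1.52) and Ighd (2.38, SE 1.69). The mean was 1.42 (adjusted p = 1.10e-04; adjusted p = 0.882 with an estimated correlation). The direction of the B cell test turned without the lymphoid-rich libraries (-0.0814), and the mean moved to 0.82 without SF_HPD 4 and 0.90 without SF_HPD 5. Cholesterol synthesis genes had negative fold changes in 17 of 19, 2 of them with an unadjusted p under 0.05, and included Dhcr7 (-0.75, SE 0.33). Their mean was -0.57 (adjusted p = 5.50e-05; adjusted p = 0.573 with an estimated correlation). The direction of the cholesterol test turned without SC_ConD 2 and 3 (0.12), and the mean moved to -0.92 without SC_ConD 1 and -0.25 without SC_ConD 2. Among unfolded protein response genes, 15 of 15 fold changes were negative, 2 with an unadjusted p under 0.05, and the list included Hyou1 (-1.23, SE 0.47) and Hspa5 (-1.19, SE 0.48). The mean was -0.49 (adjusted p = 1.10e-04; adjusted p = 0.573 with an estimated correlation). The direction of the unfolded protein test turned without SC_ConD 2 and 3 (0.15), and the mean moved to -0.81 without SC_ConD 1 and -0.21 without SC_ConD 2. Interferon-stimulated genes had negative fold changes in 17 of 20, 2 of them with an unadjusted p under 0.05, and included the guanylate-binding protein gene Gbp2 (-1.93, SE 0.67) and the RNA sensor gene Ifih1 (-0.78, SE 0.35). Their mean was -0.57 (adjusted p = 1.25e-04; adjusted p = 0.573 with an estimated correlation). The interferon call ended without SC_ConD 2 and 3 (-0.0524), and the mean moved to -0.33 without SC_ConD 2. Among erythroid markers, 5 of 5 fold changes were negative, 0 with an unadjusted p under 0.05, and the list included the globin genes Hbb-bs (-1.46, SE 0.80) and Hba-a1 (-1.35, SE 0.75). The mean was -1.11 (adjusted p = 0.00134; adjusted p = 0.573 with an estimated correlation). The erythroid call ended without SC_ConD 2 (-0.57) and SC_ConD 2 and 3 (-0.19). Amino acid stress response genes had negative fold changes in 13 of 17, 2 of them with an unadjusted p under 0.05, and included Cth (-1.23, SE 0.42) and Trib3 (-1.36, SE 0.55). Their mean was -0.50 (adjusted p = 0.00401; adjusted p = 0.573 with an estimated correlation). The stress response call ended without SF_HPD 2 (-0.33), SC_ConD 2 and 3 (0.00553) and SF_HPD 2 and 4 (-0.23), and the mean moved to -0.75 without SC_ConD 1 and -0.31 without SC_ConD 2.

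Lists of fat cell identity and metabolism genes were called lower at the preset correlation only, and none of them with an estimated correlation. Brown and beige adipocyte genes were not called (mean -0.19, adjusted p = 0.811). Among adipocyte identity genes, 16 of 18 fold changes were negative, 1 with an unadjusted p under 0.05, and the list included the adipogenic regulator gene Pparg (-0.996, SE 0.45) and the adipokine gene Retn (-2.47, SE 1.20). The mean was -0.92 (adjusted p = 0.00229; adjusted p = 0.882 with an estimated correlation). The adipocyte call ended without SC_ConD 1 (-0.78). The direction of its test turned without SF_HPD 2, the mean staying negative (-0.0307), and without SF_HPD 2 and 4 (0.15). Lipolysis and fatty acid oxidation genes had negative fold changes in 18 of 21, 1 of them with an unadjusted p under 0.05, and included the lipase coactivator gene Abhd5 (-0.89, SE 0.51). Their mean was -0.40 (adjusted p = 0.0141; adjusted p = 0.882 with an estimated correlation). The lipolysis call ended without SF_HPD 2 (-0.0484). The direction of its test turned without SC_ConD 1, the mean staying negative (-0.0135), and without SF_HPD 2 and 4 (0.0832). The lipolysis mean moved to -0.64 without SF_HPD 1, -0.65 without SC_ConD 3 and -1.18 without SC_ConD 2 and 3. Among de novo lipogenesis genes, 15 of 20 fold changes were negative, 2 with an unadjusted p under 0.05, and the list included Thrsp (-2.48, SE 1.04) and the desaturase gene Scd1 (-2.63, SE 1.21). The mean was -0.50 (adjusted p = 0.0436; adjusted p = 0.882 with an estimated correlation). The lipogenesis call ended without SF_HPD 2 (-0.16), SF_HPD 3 (-0.44) and SF_HPD 2 and 4 (-0.10). The direction of its test turned without SC_ConD 1, the mean staying negative (-0.0693). The lipogenesis mean moved to -0.77 without SF_HPD 1, -0.77 without SC_ConD 3 and -1.35 without SC_ConD 2 and 3. Branched-chain amino acid catabolism genes had negative fold changes in 16 of 21, 0 of them with an unadjusted p under 0.05, and included Hibch (-1.07, SE 0.55) and Bckdhb (-1.01, SE 0.54). Their mean was -0.33 (adjusted p = 0.00912; adjusted p = 0.882 with an estimated correlation). The branched-chain call ended after TPM rescaling (-0.0715), without SF_HPD 2 (-0.11), without SC_ConD 1 (-0.24) and without SF_HPD 2 and 4 (-0.0394), and the mean moved to -0.52 without SC_ConD 2 and 3. Among oxidative phosphorylation genes, 36 of 39 fold changes were negative, 0 with an unadjusted p under 0.05, and the list included Ndufa9 (-0.56, SE 0.49) and Cox7a2 (-1.02, SE 1.005). The mean was -0.35 (adjusted p = 0.0125; adjusted p = 0.977 with an estimated correlation). The oxidative phosphorylation call ended without SF_HPD 1 (-0.14), SF_HPD 4 (-0.17) and SF_HPD 2 and 4 (-0.34), and its direction turned without SC_ConD 2 (0.11) and SC_ConD 2 and 3 (0.46). The oxidative phosphorylation mean moved to -0.59 without SF_HPD 5 and -0.76 without SC_ConD 1.

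Inflammatory mediators had negative fold changes in 12 of 19, 4 of them with an unadjusted p under 0.05, and included Lcn2 (-3.97, SE 1.12), Saa3 (-3.82, SE 1.28), Cxcl9 (-3.35, SE 1.06) and Cxcl1 (-2.03, SE 0.60). Their mean was -0.75 (adjusted p = 0.0141; adjusted p = 0.882 with an estimated correlation). The inflammatory call ended without SF_HPD 1 (-0.58), SF_HPD 2 (-0.60), SC_ConD 2 (-0.43), SC_ConD 3 (-0.44) and SF_HPD 2 and 4 (-0.56), and its direction turned without SC_ConD 2 and 3 (0.50). The inflammatory mean moved to -1.37 without SC_ConD 1. Lcn2 and Saa3 encode acute-phase proteins, Cxcl9 and Cxcl1 chemokines, and the list's median was -0.12. Among epithelial markers, 10 of 12 fold changes were negative, 1 with an unadjusted p under 0.05, and the list included Cldn3 (-2.86, SE 1.05) and Elf5 (-0.76, SE 0.54). The mean was -0.93 (adjusted p = 0.0141; adjusted p = 0.882 with an estimated correlation). The epithelial call ended without SF_HPD 4 (-0.13), SF_HPD 5 (-0.70), SC_ConD 1 (-0.61) and SC_ConD 3 (-0.41), and its direction turned without the lymphoid-rich libraries (0.43). The epithelial mean moved to -1.56 without SF_HPD 2, -1.76 without SC_ConD 2 and -1.56 without SC_ConD 2 and 3. Glucocorticoid-responsive genes had negative fold changes in 11 of 16, 2 of them with an unadjusted p under 0.05, and included Errfi1 (-1.63, SE 0.68) and Fkbp5 (-1.06, SE 0.47). Their mean was -0.48 (adjusted p = 0.0455; adjusted p = 0.882 with an estimated correlation). The glucocorticoid call ended without SF_HPD 2 (-0.30), SF_HPD 3 (-0.48), SF_HPD 4 (-0.41), SF_HPD 5 (-0.51), SC_ConD 1 (-0.70), SC_ConD 2 (-0.35), SC_ConD 3 (-0.39), the lymphoid-rich libraries (-0.43) and SF_HPD 2 and 4 (-0.15). The direction of its test turned without SC_ConD 2 and 3, the mean staying negative (-0.0407). With the replicate number as a block the calls of 4 lists ended. These were B cell and lymph node markers (adjusted p = 0.527, over that list's alternatives 2.55e-06 to 0.977), epithelial markers (0.618, 1.29e-09 to 0.977), lipogenesis (0.126, 9.70e-06 to 0.977) and glucocorticoid-responsive genes (0.123, 3.57e-04 to 0.989), with means of 0.18, -0.15, -0.47 and -0.40. Lists not called above but called with the block were neutrophil markers (mean -0.23, adjusted p = 0.801 without the block; -0.92, adjusted p = 0.00657 with it, over that list's alternatives 1.61e-04 to 0.990) and mitochondrially encoded genes (mean -0.65, adjusted p = 0.123 without the block; -1.25, adjusted p = 5.38e-04 with it, over that list's alternatives 1.62e-19 to 0.977).

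Camera with an estimated correlation called 0 of 33 lists, 2 having an unadjusted p under 0.05, and fry called 0, with 1 under 0.05 and a smallest adjusted p of 0.696. Over the alternatives run, the highest adjusted p of each of these 15 lists lay between 0.696 and 0.990, and the lowest between 1.29e-09 and 8.53e-04. Among the 9 libraries of lower length trend the calls of the lipogenesis (-0.49), lipolysis (-0.31) and oxidative phosphorylation (-0.24) lists ended, and the direction of the epithelial test turned (0.48). Adjusted over the list alone, 4 genes passed, Lcn2, Saa3, Cxcl9 and Cxcl1, while over all genes none did. Again no adjustment was made over the 33 lists. Lcn2 was at 398 and 335 FPKM in SC_ConD 2 and 3 but at 16.8 FPKM in SC_ConD 1, below SF_HPD 3 (56.3 FPKM). Cxcl1 was at 11.2 and 8.40 FPKM in SC_ConD 2 and 3, but at 0.316 FPKM in SC_ConD 1, below SF_HPD 3 (0.679 FPKM). T and NK cell markers (mean 0.60, adjusted p = 0.123) and macrophage markers (mean -0.11, adjusted p = 0.715) were not called. Signs differed for matrix genes (mean -0.05, median 0.10), muscle markers (mean -0.15, median 0.10) and glycolysis genes (mean 0.03, median -0.02, test downward), none of them called.

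Limma called 0 of 14421 genes between SF_HPD and SC_ConD, with a smallest adjusted p of 0.394. At an unadjusted p under 0.05 there were 531 genes, against 721 expected if p values were uniform, and limma-voom called 0, with 459. Named on the lower side were Apoh (-4.46, SE 0.86), Apof (-3.99, SE 0.79), Kng1 (-4.43, SE 0.91), Proc (-3.15, SE 0.66) and Gc (-5.31, SE 1.12), all of them genes of plasma proteins. Named on the higher side were Ccnb2 (1.54, SE 0.45), Zfp422 (1.05, SE 0.32), Hsdl1 (0.90, SE 0.30), Mir22hg (0.95, SE 0.34) and Cybc1 (1.14, SE 0.45), and none passed. Lep had a log2 fold change of -1.19 (SE 1.14), Adipoq of -1.77 (SE 1.25), Tnf of 0.62 (SE 0.42) and Ccl2 of -0.98 (SE 0.73). Without SF_HPD 2 those of Lep and Adipoq moved to -0.15 and -0.62, and with single libraries left out these 4 ran from -1.79 to -0.15, -2.25 to -0.62, 0.43 to 0.81 and -2.09 to -0.37. Those of Adgre1 and Ucp1, -0.14 (SE 0.66) and -0.01 (SE 1.48), turned to 0.14 and 0.20 after TPM rescaling, and that of Ucp1 to 0.00956 with median-of-ratios factors. With single libraries left out these 2 ran from -0.56 to 0.25 and from -1.20 to 1.19. Of the 9545 named genes 144 had no overlap between the groups, and chance gives 3.57%. Without SC_ConD 1, 196 genes were called, 193 of them higher in SC_ConD, and these calls held 21 of the 22 liver markers. Without SF_HPD 5, 1 gene was called, Gm22478 again (log2 fold change 2.03, limma adjusted p = 0.0452).

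Whether the diet shifted genes against the difference seen with sleep fragmentation was asked by setting the first comparison against the second. No gene was called in opposite directions, since limma and limma-voom called 0 in either, against 828 and 273 with an unadjusted p under 0.05 by limma. The fold changes of both comparisons had a correlation of -0.470 across genes, which are not independent replicates. Both share the SF_ConD libraries, and unchanged groups that shared them gave a mean correlation of -0.369 ± 0.391 (SD over 100 draws), with 49 of the 100 draws at or below the observed value. The covariance was -0.148 against a simulated -0.119, a difference of -0.0293. With the SF_ConD libraries split so that the comparisons shared none, the correlation averaged -0.164 over 10 splits and ran from -0.344 to 0.166, with a mean covariance of -0.0596.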

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

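The tests of the lymphoid and liver patterns, those of the length trend, its use as a covariate included, and the use of unadjusted p and list counts over other splits were chosen after the data were seen. For the covariate alone, the bounds on its count of genes were written before that fit was run. Among 90 groups of 5 libraries examined, 12 had a highest or lowest library set apart from its nearest neighbour by more than 0.71 of the group's range, and chance flags about 1 in 20 groups.

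SF_HPD 2 stood apart in the adipocyte identity list (gap 0.789 of the range, mean 3.73 against 7.63 in the nearest library), in Adipoq (0.733) and in cholesterol synthesis genes (0.827). SF_HPD 4 stood apart in skeletal muscle markers (0.921, mean 8.27 against 1.33) and glycolysis genes (0.937). SF_HPD 5 stood apart in Ucp1 (0.735). SF_ConD 5 stood apart in mitochondrially encoded genes (0.810) and in the mitochondrial read share (0.738, 33.2% against 17.0%). SF_ConD 2 stood apart in cholesterol synthesis (0.917), skeletal muscle markers (0.752) and glycolysis (0.744), and SF_ConD 3 in stromal progenitor markers (0.756).

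Lymphoid transcripts were high in 5 of the 10 sleep-fragmented libraries. The tables argue against a rise shared by every sleep-fragmented mouse, since 6 of the 10 lay above the highest SC_ConD library, and against the transcript-length trend, which ran from -0.436 to 0.484 in these 5. RNA from a lymph node taken with the pad may account for the pattern, but of the 3 vessel markers outside the B cell list only 1, Glycam1, exceeded in all 5 libraries the highest of the other 8, so this stays open. Chst4 (0.619 to 4.44 FPKM against at most 1.51) and Madcam1 (1.27 to 3.86 FPKM against at most 1.41) overlapped, another 4 of the 7 vessel and stromal markers are in the B cell list, and 3 of the 7 are at 1 FPKM or more in the median library. The list's means fall into separate clusters, and within the 8 lower libraries they correlated with the vessel markers at Pearson r 0.30 (exact permutation p = 0.467, 0.86 without the 2 farthest libraries) and Spearman rho 0.43 (exact permutation p = 0.299, 0.66 without them). Those 8 libraries lack the pattern, with Glycam1 at no more than 0.796 FPKM, so this correlation cannot decide the question.

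Liver transcripts were high in SC_ConD 2 and 3, where 22 of 22 liver markers exceeded the highest of the other 11 libraries, 16 of them being at 1 FPKM or more in the median library too. The tables argue against a fall shared by every sleep-fragmented mouse, since SC_ConD 1 lay below the highest sleep-fragmented library in the mean of these markers (difference -1.28 on the log2 scale). RNA or reads from liver in these libraries may account for the pattern, and the labels give no step at which they entered. Recovered reads on 4 Y-linked genes, none of them at 1 FPKM in the median library, numbered 460 and 242 in SC_ConD 2 and 3. Elsewhere they numbered at most 29, in SF_ConD 4, and next 8, in SF_ConD 2. They numbered 0 in SF_HPD 1, 2 and 5, SF_ConD 3 and 5 and SC_ConD 1. The lower of the 2 over the highest other library was 8.34 (95% Poisson interval 5.66 to 12.7) by reads, as the test was set, and 10.1 (6.88 to 15.4) after scaling to each library's recovered total. These intervals cover counting error only, since reads are not independent molecules. The bound set for RNA from another animal of the other sex was 10, written after the data were seen. Taken against SF_ConD 4 alone, the 2 ratios fall on either side of it. The bound therefore cannot decide this explanation, which stays open.

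Libraries differed in how their expression leaned toward long or short genes, with Spearman rho across genes from -0.436 to 0.563. A group difference gave an exact permutation p of 0.946 over 72072 regroupings, and each group held libraries of both signs, which argues against the groups as the source. With the trend as a covariate, as a test for a trend that hides group differences, limma called 0 genes in each comparison, with 1680, 663 and 1017 at an unadjusted p under 0.05 (828, 273 and 531 without it). Within the 9 libraries of low trend 162 and 172 genes were called against SC_ConD, and there SC_ConD consists of the 2 libraries with liver transcripts, with 17 and 20 of the 22 liver markers among the calls. No source of the trend other than the groups was tested, and its source stays open.

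Other splits of the same libraries did not exclude chance. The numbers of splits below include the real grouping, and the highest other values leave it out. Over the splits the median count of genes at an unadjusted p under 0.05 was 197.5 for SF_ConD against SC_ConD. It was 265.5 for SF_HPD against SF_ConD and 671.5 for SF_HPD against SC_ConD. For SF_ConD against SC_ConD, 9 of 56 splits gave as many genes at an unadjusted p under 0.05 (828, highest other 2129) and 44 of 56 as many lists (10, highest other 22). For SF_HPD against SF_ConD these were 49 of 100 drawn splits (273, highest other 3589) and 81 of 100 (12, highest other 21). For SF_HPD against SC_ConD they were 34 of 56 (531, highest other 6923) and 16 of 56 (15, highest other 21). The 8 splits that part all 3 numbered pairs are too few for a share under 0.05 (531 genes, highest other 539; 15 lists, highest other 20). Genes were called by limma in 5 of 56, 5 of 100 and 12 of 56 splits, up to 458, 750 and 5673 genes. The remaining splits called 0, as did the real groups by limma and by limma-voom. The calls in the few splits that gave any point to a structure of the libraries other than their groups.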

How the results depend on the processing

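Settings with sets of libraries left out, covariates for length or tissue scores, and limma-voom were chosen after seeing the data. The count of genes called by limma stayed at 0 in each comparison under the pseudocount, filters, scalings, eBayes settings, the fit of only the groups compared and a minimum fold change, and by limma-voom. Array weights called 271 genes for SF_ConD against SC_ConD and 148 for SF_HPD against SC_ConD, with 21 and 17 of the 22 liver markers among them. With each library left out in turn the counts ran from 0 to 194, 0 to 1 and 0 to 196; the highest against SC_ConD came without SC_ConD 1, and 1 gene was called without SF_HPD 5. The 9 libraries of low length trend called 162 and 172 genes against SC_ConD. Genes in opposite directions numbered 0 under each setting run, the splits of SF_ConD included. Apart from those splits, SF_HPD against SF_ConD called 0 genes, or 1 without SF_HPD 5, where SF_ConD against SC_ConD called 0. There the count was bound to be 0, so it shows no stability. TPM rescaling moved the median log2 fold change of all genes to 0.151, 0.0592 and 0.248. Recovered reads differed little between libraries (14815592 to 18303302), and genes near the filter of 1 FPKM have the fewest reads behind them. Genes above 0 FPKM numbered 15284 in SC_ConD 3, 16750 in SC_ConD 2 and 20397 in SC_ConD 1. In the sleep-fragmented libraries they numbered 17035 (SF_HPD 2) to 23629 (SF_HPD 4). Genes of at least 1 FPKM ran from 11433 to 13182. Ccnb2 and Tnf were listed at 0 in SC_ConD 2 and 3 and at 0.349 and 0.253 FPKM in SC_ConD 1. Whether low detection bears on these genes was not tested.

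Lists called numbered 10, 12 and 15, and 0 in each comparison with an estimated correlation and with fry. With single libraries left out they ran from 9 to 16, 11 to 20 and 10 to 16, the highest coming without SF_ConD 2, SF_HPD 1 and SF_HPD 1. For SF_HPD against SC_ConD they numbered 9 with a mean FPKM of at least 5 and 8 without SF_HPD 2 and 4. The replicate block called 0 genes in each comparison (499, 342 and 417 at an unadjusted p under 0.05) and 13, 14 and 13 lists. In SF_HPD against SC_ConD it changed the 6 calls given in the report and no other. Between SC_ConD and SF_HPD 1 of 3 same-numbered correlations was highest with its own number. In the other comparisons they ran from -0.558 to 0.190 between SC_ConD and SF_ConD (0 of 3) and from -0.670 to 0.405 between SF_ConD and SF_HPD (2 of 5). In these other comparisons the block changed 5 and 2 calls, MHC class II genes in SF_ConD vs SC_ConD having a mean of 0.48 and no call. Of 37 list results 18 kept their direction in each setting run, and of 119 gene results 87 did; lists lost their call 205 times and genes gained one 49 times. The values below are log2 fold changes, means for lists, whose direction is that of the test, and the cause was not tested.

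The direction turned in these results. With a pseudocount of 0.1 this was Ccl2 -0.0371 in SF_HPD vs SF_ConD, and Ucp1 0.0424 in SF_HPD vs SC_ConD. With TPM rescaling this was Ucp1 0.20, Adgre1 0.14 in SF_HPD vs SC_ConD. With median-of-ratios size factors this was Ucp1 0.00956 in SF_HPD vs SC_ConD. With array weights this was Adipoq 0.30 in SF_HPD vs SF_ConD, and Lep 0.46, Ucp1 0.83, Adgre1 0.63 in SF_HPD vs SC_ConD. With the replicate block this was Adgre1 0.0189 in SF_HPD vs SC_ConD. With limma-voom on recovered reads this was Ccl2 -0.0977 in SF_HPD vs SF_ConD, and Ucp1 0.0711 in SF_HPD vs SC_ConD. With the lymphoid-rich libraries left out this was MHC class II list -0.58 in SF_ConD vs SC_ConD, and skeletal muscle markers list -0.38, cell cycle list 0.20 in SF_HPD vs SF_ConD, and B cell and lymph node markers list -0.0814, mammary and other epithelial markers list 0.43, Adgre1 0.0433 in SF_HPD vs SC_ConD. With SC_ConD 2 and 3 left out this was oxidative phosphorylation list 0.44, skeletal muscle markers list 0.42, unfolded protein response list 0.19, Adipoq 0.0817, Ucp1 -1.71, Ccl2 1.20, Ndufa9 0.17, Ndufa4 0.69, Gdf15 0.73 in SF_ConD vs SC_ConD, and inflammatory mediators list 0.50, oxidative phosphorylation list 0.46, cholesterol synthesis list 0.12, glucocorticoid-responsive genes list -0.0407, unfolded protein response list 0.15, Ccl2 1.23, Adgre1 0.0930, Ndufa9 0.16, Cox7a2 0.86, Errfi1 0.41, Bckdhb 0.00453 in SF_HPD vs SC_ConD. With SF_HPD 2 and 4 left out this was Adipoq 0.61, Ucp1 0.15 in SF_HPD vs SF_ConD, and adipocyte identity list 0.15, lipolysis and fatty acid oxidation list 0.0832, Ucp1 0.85, Adgre1 0.54 in SF_HPD vs SC_ConD. With the 9 libraries of low length trend this was mammary and other epithelial markers list 0.48, Ucp1 1.43 in SF_HPD vs SC_ConD. With lymphoid, liver and length scores as covariates this was T and NK cell markers list -0.26, MHC class II list -0.17, skeletal muscle markers list 0.79, unfolded protein response list 0.0812, Adipoq 0.0795, Ucp1 -1.75, Adgre1 0.0815, H2-Ob -0.0671, Cth 0.17, Hyou1 0.0234, Hspa5 0.0536 in SF_ConD vs SC_ConD, and cell cycle list 0.0482 in SF_HPD vs SF_ConD, and cholesterol synthesis list 0.16, erythroid markers list 0.0300, glucocorticoid-responsive genes list 0.45, amino acid stress response list 0.0669, unfolded protein response list 0.20, Cybc1 -0.16, Tnf -0.13, Ccl2 0.12, Adgre1 0.62, Cxcl1 0.25, Ighd -0.0846, Dhcr7 0.22, Errfi1 1.37, Cth 0.36, Hyou1 0.20, Hspa5 0.32 in SF_HPD vs SC_ConD. Over single libraries left out it turned, with these ranges, for Ucp1, SF_HPD vs SC_ConD (-1.20 to 1.19), adipocyte identity list, SF_HPD vs SC_ConD (-1.27 to -0.0307), Adipoq, SF_HPD vs SF_ConD (-1.33 to 0.25), Adgre1, SF_HPD vs SC_ConD (-0.56 to 0.25), Ccl2, SF_HPD vs SF_ConD (-0.23 to 0.25), Adgre1, SF_HPD vs SF_ConD (-0.15 to 0.66), de novo lipogenesis list, SF_HPD vs SC_ConD (-0.77 to -0.0693), lipolysis and fatty acid oxidation list, SF_HPD vs SC_ConD (-0.65 to -0.0135), oxidative phosphorylation list, SF_ConD vs SC_ConD (-0.78 to 0.0822), oxidative phosphorylation list, SF_HPD vs SC_ConD (-0.76 to 0.11), Ucp1, SF_ConD vs SC_ConD (-0.41 to 1.89).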

Other observations

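Output genes of the circadian clock showed values not described above. In SF_HPD against SF_ConD, Per3 was at 4.75 ± 3.56 against 1.78 ± 1.33 FPKM and Tef at 25.1 ± 13.2 against 14.4 ± 6.37 FPKM (SD, n = 5 each), and 11 of 18 circadian clock genes had positive fold changes. Both genes were highest, in each group, in the libraries with a length trend above 0.3. Per3 was at 8.92 and 8.13 FPKM in SF_HPD 1 and 4 and at 1.08 to 3.45 FPKM in SF_HPD 2, 3 and 5, and at 3.76 FPKM in SF_ConD 3 and 0.461 to 2.35 FPKM in the other 4 of its group. Tef was at 40.5 and 36.8 FPKM against 8.85 to 19.7 FPKM, and at 21.7 FPKM against 6.38 to 18.2 FPKM, so the group means of both genes follow these libraries. The clock list was not called (camera adjusted p = 0.118). Glucocorticoid-responsive genes went both ways in that comparison, with Dusp1 at a log2 fold change of 1.32 (SE 0.44) and Fkbp5 at -1.20 (SE 0.41), and that list was not called (camera adjusted p = 0.387).

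Looked at only after the data were seen, Xist, the long RNA of the inactive X chromosome, held 6137 to 12190 recovered reads (17.6 to 39.4 FPKM) in SF_HPD 1, SF_HPD 4, SF_ConD 3 and SC_ConD 1, and 229 to 879 reads in the other 9 libraries. These 4 libraries were also the ones with a length trend above 0.3, at 0.563, 0.484, 0.485 and 0.559. Xist is a long transcript, and no sex of the mice is given in the sources used here. Y-linked reads numbered 0 in SF_HPD 1, SF_ConD 3 and SC_ConD 1 and 2 in SF_HPD 4. In the 9 libraries lower in Xist they ran from 0, in SF_HPD 2, SF_HPD 5 and SF_ConD 5, to 460 in SC_ConD 2. Low Xist alone therefore did not mark libraries with Y-linked reads.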
